A study of Homo sapiens with 18 samples.

How the data were processed

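Whole-transcriptome RNA-seq was analysed for 18 libraries of K562 cells transfected with gapmers against the circPCMTD1 backsplice junction or with scrambled gapmers. Per the labels' protocols, cells were collected 48 hours after transfection and libraries were made with a directional kit after ribosomal RNA depletion. The labels name the oligonucleotides gapmers in the protocols and siRNA in the descriptions, and gapmers are taken here. Per the submitters' processing notes, the authors used Trim Galore, STAR and featureCounts on GRCh38, and versions, the gene annotation and the strand setting are not given in the sources used here. The deposited table holds whole-number counts per gene symbol, not normalized, for 27781 genes, of which 23225 had a count in any library. A total-RNA count per gene mixes linear and circular RNA, and where the strand setting is unknown, reads of overlapping antisense genes may be counted together.

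Groups came from the sample labels. The 3 technical libraries of each biological replicate were summed, giving 3 against 3 samples. Library totals ran from 19118533 to 29432699 counts and sums from 63851576 to 76087774. No pair of columns was identical.

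Counts were tested in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM factors, robust quasi-likelihood fits and Benjamini-Hochberg adjustment over 15678 genes, and genes at an adjusted p below 0.05 were called. Log2 CPM values in the list tests, GC trends and comparisons of spread used a prior count of 2, and log2 fold changes came from the fits. CPM values were computed with TMM-scaled library sizes, and errors on CPM are SDs over 3 summed replicates. The 35 gene lists were fixed before the data were examined and the 33 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry beside it. PCMTD1 was also tested by exact permutation of log2 CPM without a prior count.

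Genes named were chosen by a rule fixed before the data were examined: PCMTD1, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and non-overlapping replicate ranges (leaving out clone names), up to 3 called members per list by smallest p or otherwise the single member with the smallest p, and all members of the BTR list. A few genes that the rule takes are not reported here. A few genes outside it are named in the closing section, where this is stated.

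Alternatives were DESeq2 1.42.0, other scaling factors and count filters, the replicate number as a block, technical libraries entered singly, as a random effect in limma-voom, summed by the other number or reduced to the first, each replicate left out, and a test against a 1.2-fold change. DESeq2 adjusted p-values given as NA were kept as NA and counted neither as calls nor as lost calls. Chosen after the data were seen were a lowess correction (span 0.3) on transcript GC content, the same with the block, and the removal of knockdown libraries 3_2 and 3_3. GC content and coordinates came from GENCODE release 29, with GC content for 96.4% of tested genes, and symbols absent there were matched through Ensembl identifiers. The 13 mitochondrially encoded genes had no GC value matched and took no correction.

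The procedure was tested on simulated counts for 15678 genes with 200 changed, drawn from the means and depths of knockdown against scrambled. It recovered 65.7% of genes changed 1.2-fold, 79.1% at 1.5-fold and 95.5% at 2-fold, with 6 false calls among 15478 unchanged genes. Genes were drawn independently, so deviations that many genes of a library share were not simulated. Changes under 1.2-fold were not simulated either, while the 2920 genes called in the data had a median absolute log2 fold change of 0.192. Analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.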

Results

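RNA was sequenced from K562 cells, a human leukemia line that carries the BCR-ABL1 fusion, after transfection with gapmers. Gapmers are short antisense oligonucleotides that recruit RNase H to cut the RNA they pair with. In the knockdown group they were directed at the backsplice junction of circPCMTD1, a circular RNA from the PCMTD1 gene. The control group received scrambled gapmers, and both groups were harvested 48 hours after transfection. Each group held 3 biological replicates with 3 technical libraries each, 18 libraries in all. The libraries held between 19118533 and 29432699 counts, and the sums per biological replicate between 63851576 and 76087774. Within each group the first number in a library name is taken here as the biological replicate and the second as the technical library.

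The first comparison concerned the gene that hosts the targeted RNA. PCMTD1, which encodes a protein with an isoaspartate methyltransferase domain, lies on the minus strand of chromosome 8 from 51817575 to 51899186 in GRCh38. Its gene-level count was 40.3% lower in knockdown cells, falling from 20.6 ± 1.13 CPM to 12.3 ± 0.515 CPM (SD, n = 3 summed replicates per group). The log2 fold change was -0.74 with an SE of 0.052 and an adjusted p of 7.57e-10 in edgeR's quasi-likelihood test. All 9 knockdown libraries lay at 14.2 CPM or less, below all 9 scrambled libraries, which lay between 18.6 and 24.1 CPM. A two-sided exact permutation test on the 6 summed samples gave p = 0.1, the smallest value that 3 against 3 samples allow. Counts per gene add reads from circular and linear RNA, so these values do not measure the circular RNA by itself.

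**Figure D1:**
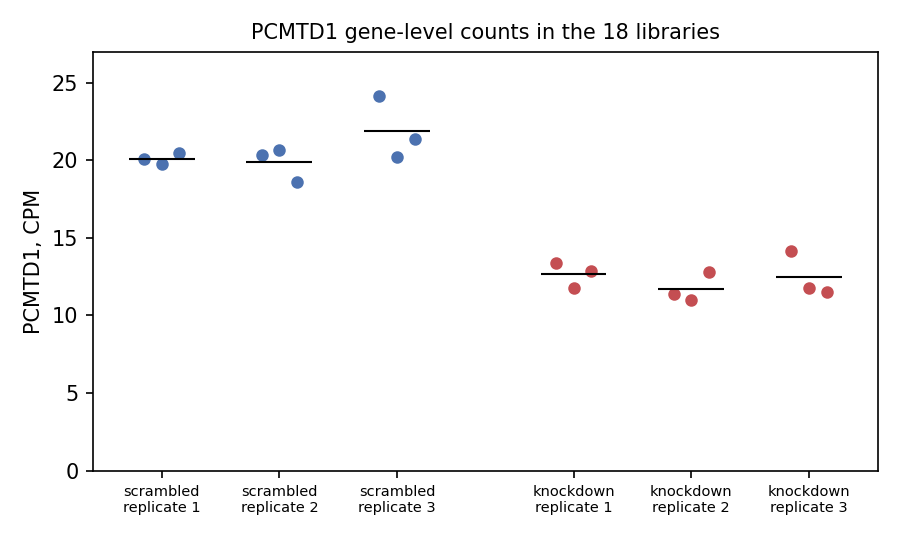
PCMTD1 in CPM, counts scaled to library size (vertical axis, from 0) for each of the 18 libraries (points), grouped by replicate, with the mean of the 3 technical libraries as a line. The knockdown libraries sit at 14.2 CPM or less and the scrambled libraries between 18.6 and 24.1 CPM.

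The main comparison asked how the transcriptome of knockdown cells differed from that of cells given scrambled gapmers. Among called genes with a mean of 5 CPM or more, the largest rises were in FAM219A on chromosome 9, which went from 1.26 ± 0.13 to 9.52 ± 0.601 CPM (SD, n = 3), and in SASH1, a signalling scaffold gene on chromosome 6, which went from 2.19 ± 0.171 to 10.5 ± 0.312 CPM. USP40, of the deubiquitinase family, rose 3.45-fold, C1GALT1, which extends O-linked glycans, 3.30-fold, and the kinesin gene KIF13B 3.05-fold. ZNF81 rose 2.61-fold, the lysosomal galactosylceramidase gene GALC 2.23-fold and ITGA2B, which encodes the platelet integrin alpha chain, 2.02-fold. Falls at that level were smaller. DIRAS3, a Ras-family GTPase gene, fell by 0.76 on the log2 scale, SLAMF6, a lymphocyte receptor gene, by 0.70, the growth factor gene IGF1 by 0.64 and DDIT4, an inhibitor of mTORC1 signalling, by 0.60.

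SLMAP and BORCS5 completed the 10 largest rises at 5 CPM or more, with log2 fold changes of 0.92 and 0.83. The other large falls, after PCMTD1 itself, were in TCN1 (-0.50), BACH2 (-0.50), DNAJB2 (-0.49), SNPH (-0.48) and ENC1 (-0.48). For each of these 20 genes all 3 knockdown replicates lay outside the range of the 3 scrambled replicates, and adjusted p in edgeR's quasi-likelihood test was 3.09e-05 or less. SEs of their log2 fold changes ran from 0.032 to 0.091.

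**Figure D2:**
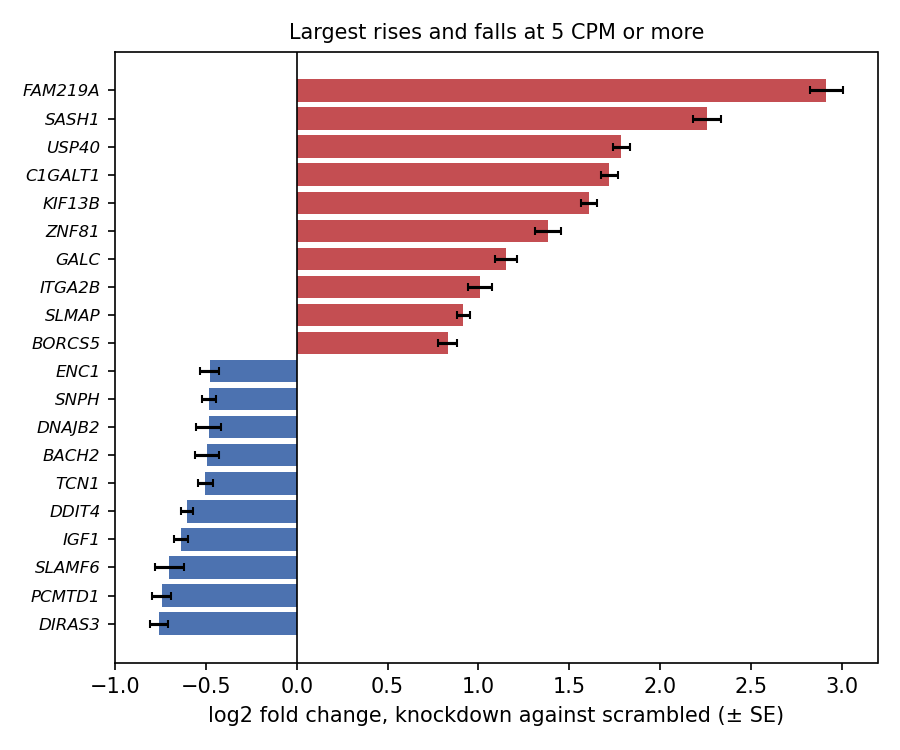
Log2 fold change of knockdown against scrambled (horizontal axis) with SE for the 10 largest rises and 10 largest falls among called genes at 5 CPM or more, from 3 summed replicates per group. FAM219A reaches 2.92 at the top and DIRAS3 -0.76 at the bottom.

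Across the 15678 genes tested, 1745 were raised and 1175 lowered in knockdown cells at an adjusted p below 0.05 in edgeR's quasi-likelihood test, 18.6% of those tested. Changes were small for most of these genes, with a median log2 fold change of 0.24 for raised and -0.15 for lowered genes. Of genes with a mean of 5 CPM or more, 8 were raised at least 2-fold by edgeR and 8 by DESeq2, and 0 were lowered at least 2-fold by edgeR, by DESeq2 or at an unadjusted p below 0.05 in edgeR. At any level, 54 called genes were raised and 18 lowered at least 2-fold by edgeR. For 34.6% of the tested genes the 3 knockdown and 3 scrambled values did not overlap, where chance gives 10%.

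The numbers of raised and lowered calls moved with the processing and with the samples used. With a GC-content correction there were 2319 raised and 2612 lowered genes, and without knockdown libraries 3_2 and 3_3 there were 2589 and 2426. Lowered calls numbered 628, 623 or 738 when scrambled replicate 1, 2 or 3 was left out, and 1023, 807 or 2280 without knockdown replicate 1, 2 or 3. Raised calls numbered 1127 without scrambled replicate 1. Fits with a replicate left out also have fewer samples. Raised genes made up 59.8% of calls in the main fit, 51.2% with libraries entered singly and 52.1% without knockdown replicate 3. Without any other single replicate they made up 58.7% to 65.6%.

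Technical and biological replicates differed by similar amounts. The median ratio of variance between biological replicates to variance within them was 1.45, and 6 of 100 random regroupings of libraries reached it. Without knockdown libraries 3_2 and 3_3 the ratio was 0.863, which 58 of 100 regroupings reached. The p-values here therefore measure a spread between samples that may be largely technical. In the same knockdown libraries, abundance deviated most with transcript GC content. The 10% of genes with the lowest GC content lay 0.10 and 0.13 (log2) above the other knockdown libraries in 3_2 and 3_3, and the 10% with the highest lay at -0.18 and -0.20. Other libraries of both groups deviated with GC content too, in either direction. Rank correlations with GC content included -0.568 in scrambled 3_1, -0.429 in knockdown 1_1 and 0.378 in scrambled 1_3. In scrambled 3_1 the genes with the lowest GC content lay at 0.093 and those with the highest at -0.06.

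**Figure D3:**
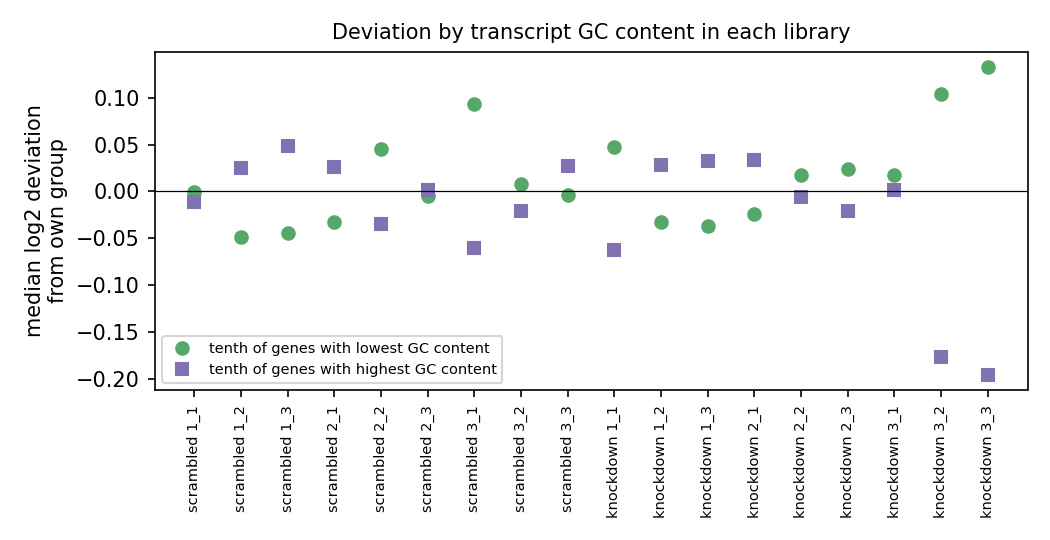
Median log2 deviation of each library from the mean of the other libraries of its group, leaving out knockdown 3_2 and 3_3 from that mean (vertical axis), for the 10% of genes with the lowest (circles) and highest (squares) transcript GC content. Knockdown libraries 3_2 and 3_3 stand at 0.10 and 0.13 for low-GC genes and at -0.18 and -0.20 for high-GC genes.

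Genes of the integrated stress response, the programme driven by the transcription factor ATF4, were lower in knockdown cells. Of 35 tested members 27 passed as lowered, and 30 when adjusted over the list alone, with a median log2 fold change of -0.20. ATF4 itself went from 313 ± 3.10 to 254 ± 4.80 CPM (SD, n = 3), and SLC3A2, which encodes a chain of amino acid transporters, had a log2 fold change of -0.29. The camera test with a preset correlation gave an adjusted p of 7.31e-16, but adjusted p = 0.219 with an estimated correlation. Without knockdown libraries 3_2 and 3_3, 27 members passed as lowered and 1 as raised, and 30 and 0 with GC correction.

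Replication-dependent histone genes were lower as well, with 30 of 39 passing as lowered, 35 when adjusted over the list alone, and a median of -0.11. H3C4 had a log2 fold change of -0.24, H4C2 of -0.22 and H1-3 of -0.18. Camera gave an adjusted p of 4.41e-13, and adjusted p = 0.361 with an estimated correlation. Genes of the same histone family can be near-identical copies, so the division of reads among those is uncertain. Lowered members numbered 33 both with GC correction and without knockdown libraries 3_2 and 3_3. MYC targets and ribosome biogenesis genes had 9 of 30 lowered, 16 when adjusted over the list alone, among them NOP16 (-0.16), GNL3 (-0.14) and NOP56 (-0.12), with camera adjusted p = 1.51e-05 and adjusted p = 0.219 with an estimated correlation. With GC correction 23 of the 30 were lowered, and 21 without those libraries.

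Lower values were called in 3 further lists, with median log2 fold changes of -0.03, -0.06 and -0.08 in the order given here. Cytosolic ribosomal protein genes had 8 lowered and 1 raised of 59 (also 8 and 1 when adjusted over the list alone), with RPSA and RPL7 at -0.09. Camera gave adjusted p = 0.0228, but 0.776 with an estimated correlation and 0.175 without scrambled replicate 1. With GC correction 19 were lowered and 4 raised, and without knockdown libraries 3_2 and 3_3 the numbers were 27 and 6. Processed copies of these genes elsewhere in the genome can share reads. NRF2 and haem oxidative response genes had 7 lowered and 1 raised of 23, or 10 and 1 when adjusted over the list alone, led by SLC7A11 (-0.32), which is also in the stress response list, with camera adjusted p = 0.046. Without knockdown libraries 3_2 and 3_3 this was adjusted p = 0.175, and it was 0.0595 to 0.162 without scrambled replicate 1 or knockdown replicate 2 or 3, 0.115 with GC correction, 0.0648 without a count filter, and adjusted p = 0.498 with an estimated correlation. In this list 12 were lowered and 4 raised with GC correction, and 12 and 5 without those libraries. Immediate early genes had 4 of 23 lowered, also 4 when adjusted over the list alone, led by ATF3 (-0.46), also in the stress response list, KLF6 (-0.34) and JUN (-0.29). Their camera adjusted p was 0.0267, 0.226 without the same libraries, 0.0563 without scrambled replicate 1, 0.128 without knockdown replicate 3, 0.0516 with GC correction and 0.0558 without a count filter, with adjusted p = 0.449 when the correlation was estimated. Here 10 were lowered with GC correction, and 6 lowered and 2 raised without those libraries.

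Interferon-stimulated genes and cholesterol synthesis genes were the lists called higher. Of 30 tested interferon-stimulated genes 8 were raised and 1 lowered, or 9 and 2 when adjusted over the list alone. IFITM1, a membrane restriction factor gene, rose from 134 ± 2.73 to 164 ± 1.86 CPM (SD, n = 3), while SAMD9 and IFI6 had log2 fold changes of 0.78 and 0.79 at mean levels under 6 CPM. Camera gave an adjusted p of 0.0137, which was 0.0782 without knockdown libraries 3_2 and 3_3, and adjusted p = 0.219 with an estimated correlation. Cholesterol synthesis had 9 of 25 raised, 11 raised and 1 lowered when adjusted over the list alone, with HMGCS1 at 0.19 and TM7SF2 at 0.28. With GC correction 13 were raised and 2 lowered, and 13 and 1 without those libraries. Of the interferon list these were 9 and 2, then 8 and 2. The cholesterol list had camera adjusted p = 0.0137, and adjusted p = 0.219 with an estimated correlation. The correlations estimated for the cholesterol and interferon lists were -0.0075 and -0.0218, below the preset 0.01. A higher correlation among members is therefore not why these p-values rose. Of the 8 lists called by camera, 0 passed with an estimated correlation after adjustment, 4 had an unadjusted p below 0.05 there, and 7 passed by fry in the same direction. Over all tested lists fry, which does not compare a list with other genes, called 3 raised and 8 lowered. Those not called by camera were megakaryocyte genes (fry adjusted p = 0.000546, raised), and circular RNA biogenesis (0.000732), nuclear oxidative phosphorylation (0.0198) and NF-kB genes (0.0491), all lowered. With an estimated correlation camera gave these 4, in the same order, adjusted p of 0.647, 0.498, 0.449 and 0.776.

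**Figure D4:**
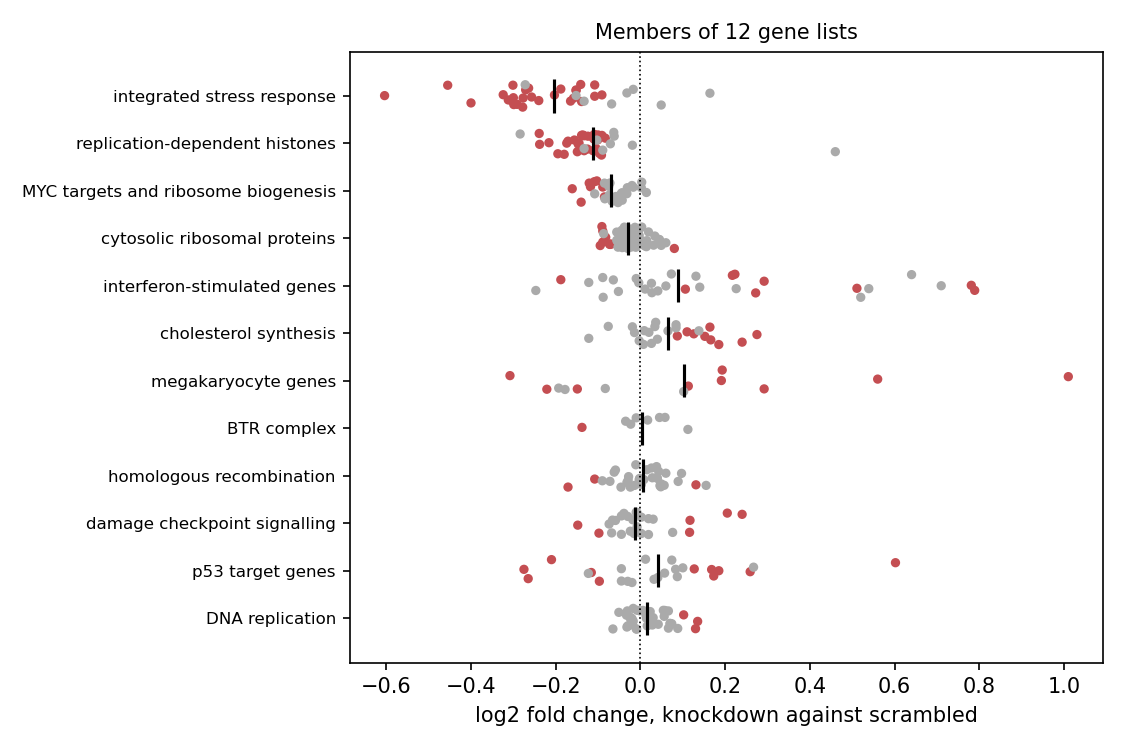
Log2 fold change of knockdown against scrambled (horizontal axis) for each tested member (points) of 12 gene lists (vertical axis), with red points past an adjusted p of 0.05 in edgeR and a black line at the list median. The stress response median lies at -0.20 and the BTR complex median at 0.00.

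The title of the series links the circular RNA to the DNA damage response, and lists for that response were examined. The counts measure RNA and not protein levels or activity, so these lists do not test that link directly. The BTR complex is the BLM helicase with TOP3A, RMI1 and RMI2, which resolves recombination intermediates, and its list adds partner genes. Of its 8 members 1 was lowered, also 1 when adjusted over the list alone, with TOP3A at -0.14 (SE 0.032, adjusted p = 0.00391 in edgeR, and 0.0549 without scrambled replicate 2). BLM was at 0.06, RMI1 at -0.04, RMI2 at 0.05, FANCM at 0.02, RPA1 at -0.01, RPA2 at -0.02 and RPA3 at 0.11, none of which passed the test. The list gave camera adjusted p = 0.965. With GC correction 2 members passed as raised and 1 as lowered, and without knockdown libraries 3_2 and 3_3 there were 0 and 1.

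Other damage and cycle lists showed scattered members rather than a called shift. Homologous recombination had 1 raised (SWI5, 0.13) and 2 lowered (UIMC1, -0.17, and MUS81, -0.11) of 34, with 0 and 1 when adjusted over the list alone (adjusted p = 0.994). Fanconi anemia genes had 1 lowered of 18, FANCA at -0.13 (adjusted p = 0.748), also 1 over the list alone, and end joining had 1 raised of 17, LIG4 at 0.21, and 0 over the list alone (adjusted p = 0.883). Mismatch and excision repair had 5 of 36 raised, including ERCC2 (0.16), GTF2H1 (0.12) and LIG1 (0.14), also 5 over the list alone (adjusted p = 0.997). Checkpoint signalling had 4 raised and 2 lowered of 26, the same numbers over the list alone, with the checkpoint adaptor gene TOPBP1 at 0.24, the ubiquitin ligase gene RNF168 at -0.15 and MDC1 at -0.10 (adjusted p = 0.705). Targets of p53 had 6 raised and 5 lowered of 25, the same over the list alone, with TNFRSF10B at -0.27, CCNG1 at 0.17 and FDXR at 0.17 (adjusted p = 0.817). DNA replication had 3 of 40 raised, PRIM2 (0.13), GINS1 (0.10) and LIG1, and 1 over the list alone (adjusted p = 0.705). E2F genes had 2 of 25 raised, among them E2F2 (0.14), also 2 over the list alone (adjusted p = 0.446), and mitosis genes had 1 of 43 lowered, KIF20A at -0.14, also 1 over the list alone (adjusted p = 0.748). P-values in brackets above are camera's, which tests for a common direction. Of all genes tested, 18.6% were called. Fry can also test for members moving either way, without comparing a list with other genes. It gave adjusted p = 8.8e-06 for both p53 targets and checkpoint signalling, 0.00011 for mismatch and excision repair and 0.00167 for E2F genes. The BTR list was at 0.0096, Fanconi anemia genes at 0.0273 and end joining at 0.0381. Mitosis genes, homologous recombination and DNA replication did not pass (0.119, 0.122 and 0.228).

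Member counts in these lists rest on the setting. With GC correction, raised and lowered numbered 2 and 6 for homologous recombination, 1 and 4 for Fanconi anemia genes, 2 and 4 for end joining, 8 and 6 for mismatch and excision repair, and 4 and 6 for checkpoint signalling. They were 6 and 6 for p53 targets, 8 and 3 for DNA replication, 6 and 1 for E2F genes and 4 and 6 for mitosis genes. Without knockdown libraries 3_2 and 3_3 the same lists, in that order, had 3 and 7, 2 and 4, 2 and 1, 6 and 6, 6 and 5, 6 and 6, 9 and 3, 5 and 0, and 2 and 12.

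K562 lineage and fusion-kinase genes moved both ways. Megakaryocyte genes had 6 raised and 3 lowered of 13, the same over the list alone, with ITGA2B at 1.01, ITGB3, its integrin partner, at 0.56 and SRGN at 0.29, and camera adjusted p = 0.363. Erythroid genes had 12 raised and 8 lowered of 43, or 15 and 9 over the list alone, with HBZ, an embryonic globin gene, at 0.30, LMO2 at 0.27 and GFI1B at 0.24 (adjusted p = 0.454). BCR-ABL1 and STAT5 or ERK outputs had 5 raised and 5 lowered of 32, or 7 and 8 over the list alone, with GAB2, an adaptor in BCR-ABL1 signalling, at -0.36, ETV4 at 0.35 and CCND1 at 0.38 (adjusted p = 0.519). With GC correction and without knockdown libraries 3_2 and 3_3, erythroid genes had 16 and 18 raised and 10 and 11 lowered, and the fusion-kinase outputs 7 and 9 raised and 11 and 10 lowered. Megakaryocyte counts stayed at 6 and 3.

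The remaining stress and metabolic lists were not called by camera. NF-kB genes had 2 raised and 2 lowered of 19, 3 and 2 over the list alone, with TNFAIP3 at -0.22, NFKB2 at 0.16 and BIRC3, under 1 CPM, at 1.02 (adjusted p = 0.501). The unfolded protein response had 3 raised and 4 lowered of 22, 4 and 4 over the list alone, with EDEM1 at -0.16, HERPUD1 at -0.22 and ERN1 at -0.17 (adjusted p = 0.748). Heat shock genes had 2 of 20 raised, also 2 over the list alone, HSPA6 at 0.22 and HSPB1 at 0.10 (adjusted p = 0.748). Apoptosis genes had 3 raised and 4 lowered of 32, 5 and 4 over the list alone, including BBC3 (-0.28) and BID (0.18), with adjusted p = 0.817. Glycolysis and hypoxia had 1 raised and 4 lowered of 34, 1 and 3 over the list alone, with SLC2A3 at 0.13, VEGFA at -0.16 and HK2 at -0.12 (adjusted p = 0.18). Nuclear oxidative phosphorylation genes had 5 of 47 lowered, 3 over the list alone, with NDUFA10 and ATP5MC1 at -0.13 and ATP5F1B at -0.07. Their adjusted p was 0.0721, and 0.016 without knockdown libraries 3_2 and 3_3, 0.0498 without scrambled replicate 3 and 0.0312 without knockdown replicate 3, but 0.449 with an estimated correlation. Their lowered members numbered 12 with GC correction and 15, with 1 raised, without knockdown libraries 3_2 and 3_3. Raised and lowered under the first and then the second of these settings were 3 and 4, then 6 and 3, for NF-kB, 8 and 4, then 7 and 4, for the unfolded protein response, and 3 and 3, then 4 and 7, for heat shock. They were 5 and 6, then 7 and 5, for apoptosis, and 2 and 12, then 5 and 11, for glycolysis and hypoxia.

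Mitochondrially encoded mRNAs had 5 raised and 1 lowered of 13, 7 and 1 over the list alone, with ND4 and COX2 at 0.12 and COX3 at 0.14. Camera gave an adjusted p of 0.132, which was 0.0492 without scrambled replicate 3 and 0.0326 without knockdown replicate 1, but 0.278 without knockdown libraries 3_2 and 3_3 and 0.415 without knockdown replicate 3, all at the preset correlation. The correlation estimated for this list was 0.786, at which the adjusted p was 0.825. The list median fell from 0.10 to 0.03 (log2) without those libraries, with 4 raised and 1 lowered. They numbered 0 and 1 in the GC-corrected fit, though no member has a GC value. Their share of counts was 2.81% and 2.73% in knockdown libraries 3_2 and 3_3, and 2.09% to 2.52% in the scrambled libraries. Abundant noncoding RNAs had 1 raised and 4 lowered of 14, 1 and 5 over the list alone, with NEAT1 at -0.16, RN7SL1 at -0.11 and MALAT1 at -0.08 (adjusted p = 0.446). RN7SL1 and RN7SL2 together took 3.40% and 3.19% of counts in knockdown 3_2 and 3_3, against 3.66% to 4.05% in the scrambled libraries. Genes that handle gapmers had 2 raised and 2 lowered of 16, the same over the list alone, with RNASEH2B at 0.18, STAB1 at 0.62 and PSPC1 at -0.13 (adjusted p = 0.569). Factors of circular RNA biogenesis had 2 raised and 3 lowered of 23, 2 and 4 over the list alone, with FTO at 0.26, YTHDF2 at -0.09 and EIF4A3 at -0.10 (adjusted p = 0.252). With GC correction 4 of these factors were raised and 9 lowered, and 3 and 9 without knockdown libraries 3_2 and 3_3. For abundant noncoding RNAs these numbers were 0 and 5, then 2 and 5, and for gapmer handling genes 2 and 5 in both.

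Markers of other cell types were sparse. Of 15 B lymphoid markers 4 were tested and 2 were raised, also 2 over the list alone. Among them RAG1 stood at 7.60 CPM in scrambled and 9.08 CPM in knockdown cells, a log2 fold change of 0.26. Of 14 T lymphoid markers 3 were tested and 1 was raised, 2 over the list alone, with CD3D at 0.46. Both lists were too small for a set test. Granulocyte and monocyte markers had 1 raised, LYZ at 0.34, and 1 lowered, ITGAM at -0.36, of 10 tested, the same over the list alone (camera adjusted p = 0.572). Epithelial and fibroblast markers had 2 raised and 2 lowered of 8, the same over the list alone, including FN1 at -0.16, COL1A1 at -0.68 and COL1A2 at 0.84, with collagen levels under 2 CPM (adjusted p = 0.978).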

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

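All tests of explanations in this part were chosen after the result was seen, except the removal of a GC trend from knockdown libraries 3_2 and 3_3, which was fixed before its outcome was known.

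In 236 groups of 9 libraries (named genes and library measures in each group), 7 held a library far from the others, fewer than the 11.8 that chance gives. PCMTD1 stood at 24.1 CPM in scrambled 3_1, the next library being at 21.3 CPM, a gap of 0.503 of the range. SLMAP was highest in scrambled 1_2 with a gap of 0.545 of the range, and EDEM1 was lowest in that library with a gap of 0.567. LIG1 was lowest in scrambled 3_2 with a gap of 0.572, and STAB1, at 2.65 CPM, was highest in scrambled 3_3 with a gap of 0.629. FANCA was lowest in knockdown 3_3, at 153 CPM with a gap of 0.604, and E2F2 was lowest in knockdown 3_2, at 60.0 CPM with a gap of 0.518.

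Knockdown libraries 3_2 and 3_3 stood apart from the other knockdown libraries, with their deviations correlated across genes at r = 0.72 (genes are not independent). A difference of the replicate's culture is argued against, because the remaining library of that replicate, 3_1, correlated with either at 0.191 at most. GC content accounts for part of the pattern, with rank correlations of -0.72 and -0.77 between deviation and GC content. Once a smooth GC trend was removed the correlation of the 2 libraries remained 0.424, above the bound of 0.3 set beforehand, so GC content by itself does not account for all of it. What else the libraries share stays open, and part of any such correlation comes from the shared baseline of the other knockdown libraries.

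The 8 genes raised at least 2-fold at 5 CPM or more, with 0 lowered by edgeR or DESeq2, were FAM219A, SASH1, USP40, C1GALT1, KIF13B, ZNF81, GALC and ITGA2B. The smallest of their log2 fold changes was 0.99 after GC correction. Median deviations with GC content reached only -0.196 (log2) in any library, so this test could hardly have failed and decides little. Across genes, the log2 fold change had a rank correlation of 0.004 with GC content. Other scalings left the smallest of the 8 at 1.01, but they move the median of all genes by only -0.0033 and 0.0058, so that test decides nothing about scaling. Cutting of these RNAs by the scrambled gapmer in control cells is an open candidate explanation, since it would give large rises with no matching falls. Their spliced transcripts shared no stretch of 9 to 12 bases more often than length-matched genes (smallest adjusted p = 0.769, 200 random sets), but introns were not searched and the gapmer sequence was not used here. An earlier search over the 15 raised genes with the smallest p found a stretch of 9 bases in 8 of them, which against length-matched sets had p = 0.06 by permutation and adjusted p = 0.239; an effect of the knockdown itself stays open too.

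The call of the lower integrated stress response was lost in camera with an estimated correlation (adjusted p = 0.219). Knockdown libraries 3_2 and 3_3 do not account for the lower values, since the list's median was -0.196 without them. After GC correction the median was -0.199. Median deviations with GC content reached only -0.196 (log2) in any library, so the GC test could hardly have failed and decides little. Whether the knockdown lowered the response or the scrambled gapmer raised it in control cells cannot be told apart, since the groups hold 0 untransfected samples.

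Of the 10 splits of the 6 samples into 3 and 3, 1 called as many genes as the real one, which was the real split itself. The real split called 2920 genes in edgeR and the highest other 0, with 4888 and at most 1176 at an unadjusted p below 0.05. Splits into 3 and 3 are too few for a share under 0.05.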

How the results depend on the processing

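Tests with a GC correction or without knockdown libraries 3_2 and 3_3 were chosen after the data were seen. PCMTD1 kept its direction and call under all 20 alternatives, with log2 fold changes from -0.78 to -0.70 and adjusted p of 2.05e-07 or less, and so did the calls of the 10 largest rises and 10 largest falls at 5 CPM or more. Of the 106 called genes named beside PCMTD1, 81 lost the call in at least 1 alternative. The 106 include the other largest rises and falls, none of which lost it. Of the 81, 39 lost the call in an alternative other than the test against a 1.2-fold change. No gene or list called in either setting reversed.

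Raised and lowered genes, 1745 and 1175, became 2213 and 1772 with the replicate block, 2137 and 2036 with libraries entered singly, 2589 and 2389 when summed by the second number, 157 and 38 against a 1.2-fold change, 2589 and 2426 without knockdown libraries 3_2 and 3_3, 2319 and 2612 with GC correction and 2320 and 2636 with the replicate block and GC correction. Leaving out each replicate gave 1127 to 2482 raised and 623 to 2280 lowered. The main fit took the samples as unpaired. Same-numbered samples deviated together at 0.261, -0.012 and 0.302. Knockdown 1 and 3 correlated best with the scrambled sample of their number, and knockdown 2 with scrambled 1 (0.198), so whether the number pairs samples stays open. With the replicate block camera called the mitochondrially encoded mRNAs (adjusted p = 0.0226) at the preset correlation and not the NRF2 list (0.079).

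Genes raised at least 2-fold, 54, were 26 with DESeq2, 20 with at least 50 counts in 3 samples, 26 singly, 24 with limma-voom and 28 against 1.2-fold, and 40 to 67 with each replicate left out. Genes lowered at least 2-fold, 18, were 4 with DESeq2, 30 without a count filter, 2 with at least 50 counts, 4 singly, 4 with limma-voom, 10 with the first technical library and 4 against 1.2-fold, and 11 to 32 with each replicate left out. Lists called raised, 2, were 0 with an estimated correlation and 1 without knockdown libraries 3_2 and 3_3. Lists called lowered, 6, were 0 with an estimated correlation, 4 with GC correction, 4 without a count filter, 8 by fry and 3 to 7 with each replicate left out. The ratio of variance between to within biological replicates, 1.45, was 0.863 without those libraries. The cause was not tested for any of these. Many genes called at 2-fold had low counts, since 20 raised and 2 lowered were called there with the 50-count filter. DESeq2, libraries entered singly and limma-voom also gave fewer. Libraries entered singly and limma-voom tested 13830 genes, against 15678 in the main fit, so they left out more genes with few counts. In DESeq2, genes with an adjusted p of NA were not counted as calls.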

Other observations

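Tests in this part were chosen after the table of all genes had been seen, and so were the lists used, so their p-values describe the data and are not independent evidence. Genes named here were chosen after their values were seen.

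Noncoding host genes of small nucleolar RNAs were lower in knockdown cells. Of 23 tested, 17 were lowered, 19 when adjusted over the list alone, with a median of -0.18 and adjusted p = 0.0045 in camera with an estimated correlation. Camera p-values in this part were adjusted over the lists of this part only. Those above were adjusted over the 33 fixed lists tested, so the values are not on the same footing. GAS5 had a log2 fold change of -0.26, SNHG32 of -0.25, SNHG1 of -0.21 and ZFAS1 of -0.18. Among lysosomal enzymes and membrane proteins 23 were raised and 2 lowered of 56, or 28 and 2 over the list alone, with IFI30 at 0.63, GRN at 0.51 and MAN2B1 at 0.32, and adjusted p = 0.0893 with an estimated correlation. With GC correction 28 of these were raised and 6 lowered, and 29 and 5 without knockdown libraries 3_2 and 3_3. For the host genes these numbers were 1 and 18, then 1 and 19.

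GC content is argued against as the whole cause for the lysosomal genes, whose median was 0.082 before and 0.074 after GC correction. For the host genes the median was -0.185 after GC correction. Deviations with GC content were too small to have moved that median far, so the test decides little for them. Host gene transcripts are targets of nonsense-mediated decay, so a hypothesis is that less of them escapes it in knockdown cells, which may also lower mRNAs of decay factors. The list of 10 decay factors gave fry p = 0.00541 towards lower values, but 1 of 10 passed the test (SMG5, at -0.19), the median was -0.04 and camera with an estimated correlation gave adjusted p = 0.0893, so the support is slight. Lowered decay factors numbered 5 with GC correction and 3 without knockdown libraries 3_2 and 3_3.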
